A study of Homo sapiens with 6 samples.

How the data were processed

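RNA of U-2 OS cells was sequenced in 6 libraries, 3 from cells expressing wild-type SRSF1 (SRSF1 WT) and 3 from cells expressing its mutant S-A. The labels name the AG RNAex Pro reagent for extraction of total RNA, the KC Digital mRNA kit for the libraries and the DNBSEQ-T7 for sequencing. The submitters' processing notes name fastp 0.20.1, HISAT2, StringTie, DESeq2, DESeq and the genome build GRCh38, without their order or settings. Whether molecular identifiers were counted, whether strand was used and which annotation release was taken are not given in the sources used here, so reads are not known to be independent molecules.

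The deposited gene table held whole-number counts per gene and library, which the authors made from the aligned reads and did not scale. It also held FPKM values that the authors scaled by gene length and library size. The log2 fold changes in the deposited table are those of the authors for S-A against WT, a direction checked against the sign of their FPKM columns. The p-values and adjusted p-values in the deposited tables come from the authors' own tests and were used only where the text says so. All 6 count columns and all 6 FPKM columns were used, and 0 per-sample columns were left out. The gene table had already been filtered by the authors, since its lowest total was 106 counts for a gene over the 6 libraries. Of its 14797 genes, 1508 had only an assembly name (MSTRG), of which 357 passed the test, and 13218 matched GENCODE release 29, which gave the coordinates and may differ from the authors' annotation.

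The deposited splicing tables have the columns of rMATS output from junction counts, with inclusion and skipping counts, inclusion levels from 0 to 1, the difference of the mean level of set 1 minus that of set 2, p-values and FDR by the authors. The columns name neither group, so directions are given only as set 1 and set 2. The sign of the difference was checked against the mean levels of both sets for every event, within 0.0015. In many fields the commas between the counts of the 3 libraries had been lost, for 30098 sets of exon skipping counts. They were split so that the inclusion levels were met within 0.00051, which left 1 reading in 18463 sets and several in 11635, where the evenest was taken. Per library, the junction counts summed to 11111624, 11879653 and 11505934 in set 1 and 10713125, 14804946 and 12145369 in set 2. The deposited gene ontology table gave terms with p-values and gene counts by the authors, without the rule for its gene list.

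Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with the group as the only term and Benjamini-Hochberg adjustment, and genes passed at an adjusted p under 0.05. The edgeR filter on low counts was applied and removed 0 genes. Levels are CPM, counts scaled to library size with the TMM factors, with the SD over libraries. Gene lists were tested on voom values with camera of limma 3.58.1, a preset correlation between genes of 0.01, and adjustment over the 35 lists with at least 5 measured genes. Camera was repeated with the correlation estimated for each list. Splicing events passed at the authors' FDR under 0.05 with a difference of at least 0.1. Directions of events were tested with an exact two-sided binomial test, and the overlap of spliced and changed genes with Fisher's exact test over the genes tested in both tables. Single values were compared with exact permutation tests, whose smallest two-sided p with 3 against 3 is 0.1. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for the rest.

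The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The 36 lists covered splicing factors (SR proteins, hnRNP proteins, core spliceosome, reported SRSF1 targets, nonsense-mediated decay), the nucleolus and ribosome (biogenesis, ribosomal proteins, RNA polymerase I, nucleolar caps and paraspeckles, small nucleolar RNA hosts, translation factors), stress and metabolism (redox, p53, integrated stress, heat shock, hypoxia, pH, oxidative phosphorylation, mitochondrial genes, autophagy, cholesterol), proliferation (DNA replication, mitosis, histones, DNA repair, MYC targets), signalling (interferon, NF-kB, immediate early), matrix and bone, and markers of epithelial, haematopoietic, endothelial, neuronal and muscle cells. Named genes are SRSF1, then the 10 largest rises and 10 largest falls among genes that passed, with a mean of at least 5 CPM in the higher group, no overlap between groups and a gene symbol. To these were added up to 3 genes with the smallest p in the list's direction from each of the 8 lists with the smallest p, and up to 3 in any direction from 7 lists fixed as central. Named events are those of SRSF1, called events of its reported targets, and per event type the 3 largest called differences in each direction, 1 per gene, with a mean of at least 20 junction counts per library and no overlap. For alternative 5' splice sites and retained introns 0 events met this rule. Some genes and events that the rule names are not reported here, and the counts of the report include them.

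The alternatives for genes were DESeq2 size factors, library totals alone, no filter, a filter on CPM above 1 in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, limma-trend on log2 FPKM with a pseudocount of 0.1 or 1 and a minimum mean of 0.5 or none, the replicate number as a block, and each library left out in turn. For lists, fry was run as well. For splicing, they were an FDR under 0.01, a difference of at least 0.2 or no minimum, a mean of at least 20 junction counts, and an edgeR test on paired inclusion and skipping counts, also with each library left out. That test used a term for each library and a quasi-likelihood dispersion alone, on events with at least 10 inclusion and 10 skipping counts in all. This form was chosen on simulated data, where one with a negative binomial dispersion found few shifts. Chosen after the data had been seen were a loess correction of each library for GC content and gene length, the use of 1 event per gene and the use of events with 1 reading of the counts.

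The gene test was tested on simulated data with 14797 genes. It recovered 4% of 50 genes changed 1.2-fold, 34% at 1.5-fold, 66% at 2-fold and 88% at 4-fold, with 12 false calls among 14597 unchanged genes. Far fewer genes were changed in these simulated data than the 6340 called in the real data, which makes the adjustment stricter. The shares are therefore not those of the real comparison. The edgeR splicing test recovered 1.49% of simulated shifts in inclusion of 0.1, 28.4% at 0.2 and 74.2% at 0.3, with 1 false call among 23117 unchanged events. The main splicing calls rest on the authors' FDR, which was not simulated. Shifts were placed only in events with a mean of at least 20 junction counts and middle inclusion levels. More events entered the test than in the real data (23317 against 10435). These shares are therefore not those of the main calls. No library was a copy of another. The chi-square statistic per gene was 11.7 to 14.7 between libraries of 1 group and 51.2 to 60.4 between libraries of different groups.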

Results

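RNA was profiled in 6 libraries from U-2 OS cells, an established human osteosarcoma line. In 3 libraries the cells expressed the wild-type form of the splicing factor SRSF1 (SRSF1 WT), and in the other 3 they expressed a mutant form that the labels call S-A. The title of the series concerns pH gradients, redox reactions, nucleolar caps and the integrity and function of the nucleolus, so the comparison asks how RNA levels and splicing differ between cells with the mutant and cells with the wild-type protein. The deposited gene table held counts and FPKM values for 14797 genes in each library. The WT libraries held 26137204, 34833584 and 29376301 counts, and the S-A libraries 26498552, 28344151 and 27885903. A second deposited table listed 58723 splicing events in 10338 genes with their junction counts, and another listed gene ontology terms for a list of spliced genes. The labels do not say that the replicates were separate cultures. P-values below for single genes, single splicing events and exact permutation tests therefore measure the spread between these libraries. Binomial, Fisher's and matched-draw p-values take events or genes as units, and camera compares a list's genes with other genes.

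SRSF1 itself was abundant in both groups. Its level was 458 ± 16.8 CPM (counts scaled to library size; SD, n = 3) in WT libraries and 521 ± 54.5 (SD, n = 3) in S-A libraries. The gene (ENSG00000136450) lies on chromosome 17 from 58003360 to 58007346 of GRCh38, and its counts include any RNA from an expressed copy that maps to it. The groups did not overlap, which chance gives in 10% of genes, and the log2 fold change was 0.19 (SE 0.07). All 3 S-A libraries lay above the 3 WT libraries, the closest at 472 CPM (S-A replicate 3) and 471 CPM (WT replicate 2). On library totals alone their order was reversed. The edgeR test gave an adjusted p of 0.0859, so the difference did not pass the threshold. The authors' own test in their deposited table did call SRSF1 higher in S-A (log2 fold change 0.19, adjusted p = 0.00575). On the authors' FPKM values SRSF1 ranged from 142 to 156 in WT and from 171 to 207 in S-A libraries. The call depended on the test and on 1 library. The adjusted p was 0.00574 with the DESeq2 Wald test, 0.0283 without S-A replicate 3 and 0.0256 to 0.0279 on FPKM, and it ranged from 0.00574 to 0.221 over all alternatives. Without S-A replicate 1 the log2 fold change was 0.10.

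**Figure D1:**
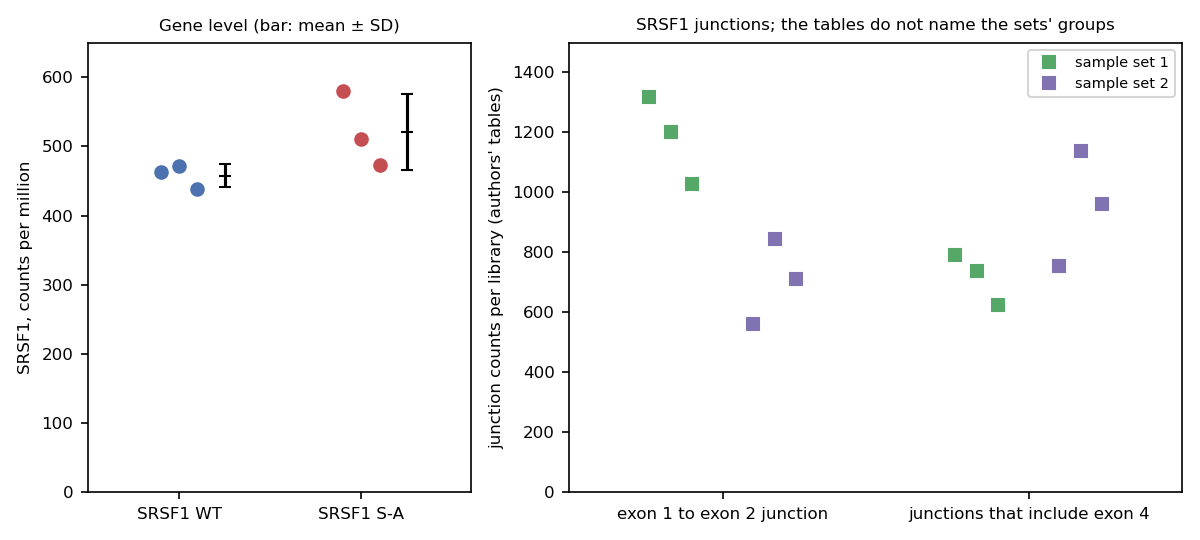
Left, SRSF1 level in CPM (TMM scaling) for each library, with the group mean and SD beside the points. All S-A libraries lie above all WT libraries with this scaling, the closest at 472 and 471, and the edgeR adjusted p is 0.0859. Right, junction counts of SRSF1 per library in the authors' splicing tables for the junction of exons 1 and 2 and for the junctions that include exon 4. The second counts sum the junctions on both sides of exon 4, so which count is larger has no meaning by itself. Relative to the second, the first is higher in all 3 libraries of set 1 than in those of set 2, but the tables do not say which group each set is.

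Cells expressing SRSF1 S-A differed from those expressing WT in the RNA levels of many genes, most of them by small steps. MMP3, a secreted protease that degrades extracellular matrix, rose from 160 ± 19.9 to 870 ± 23.2 CPM (SD, n = 3 per group), which is 5.44-fold. G0S2, an inhibitor of triglyceride breakdown, rose from a low level of 0.727 ± 0.283 to 8.06 ± 1.17 CPM, a log2 fold change of 3.46. The matrix proteoglycan gene DCN fell 11.7-fold, from 17.9 ± 0.964 to 1.52 ± 0.0674 CPM, and CXCL14, which encodes a chemokine, fell 7.10-fold, from 51.3 ± 1.71 to 7.22 ± 0.117.

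The other 8 of the 10 largest rises, with log2 fold changes in parentheses, were INSYN2B (2.60), MYCT1 (2.49), PNLIPRP3 (2.46), ARHGDIB (2.42), ATP6V0D2 (2.09), which encodes a subunit of the vacuolar proton pump, the potassium channel gene KCNQ3 (2.07), CNKSR1 (1.99) and the focal adhesion gene LPXN, which rose 3.99-fold. Further genes with large falls were PRSS23 (-3.27), DEUP1 (-3.02), LRMDA (-2.71), CDK15 (-2.40), PPP2R2B (-2.38), the fungal pattern receptor gene CLEC7A (-2.31) and the atypical cadherin gene FAT3 (-2.27). Among these rises and falls, the smallest adjusted p was 4.73e-06 for CXCL14 and the largest was 0.00164 for PNLIPRP3. MMP3 (ENSG00000149968) lies on chromosome 11 from 102835801 to 102843803, G0S2 (ENSG00000123689) on chromosome 1 from 209675420 to 209676388, DCN (ENSG00000011465) on chromosome 12 from 91140484 to 91183123 and CXCL14 (ENSG00000145824) on chromosome 5 from 135570679 to 135579279.

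In all, 3141 genes rose and 3199 fell, which is 42.8% of the 14797 tested. Only 323 of the rises and 316 of the falls reached a 2-fold change, the median size among the called genes was 0.38 on the log2 scale, and 4569 of them (72.1%) changed by less than 1.5-fold. The groups did not overlap in 8239 genes (55.7%), where chance gives 10%. The authors' deposited table called 3196 genes higher and 3031 lower in S-A at the same threshold, and 5873 calls were shared. The first principal component held 37.3% of the variance and separated the groups.

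**Figure D2:**
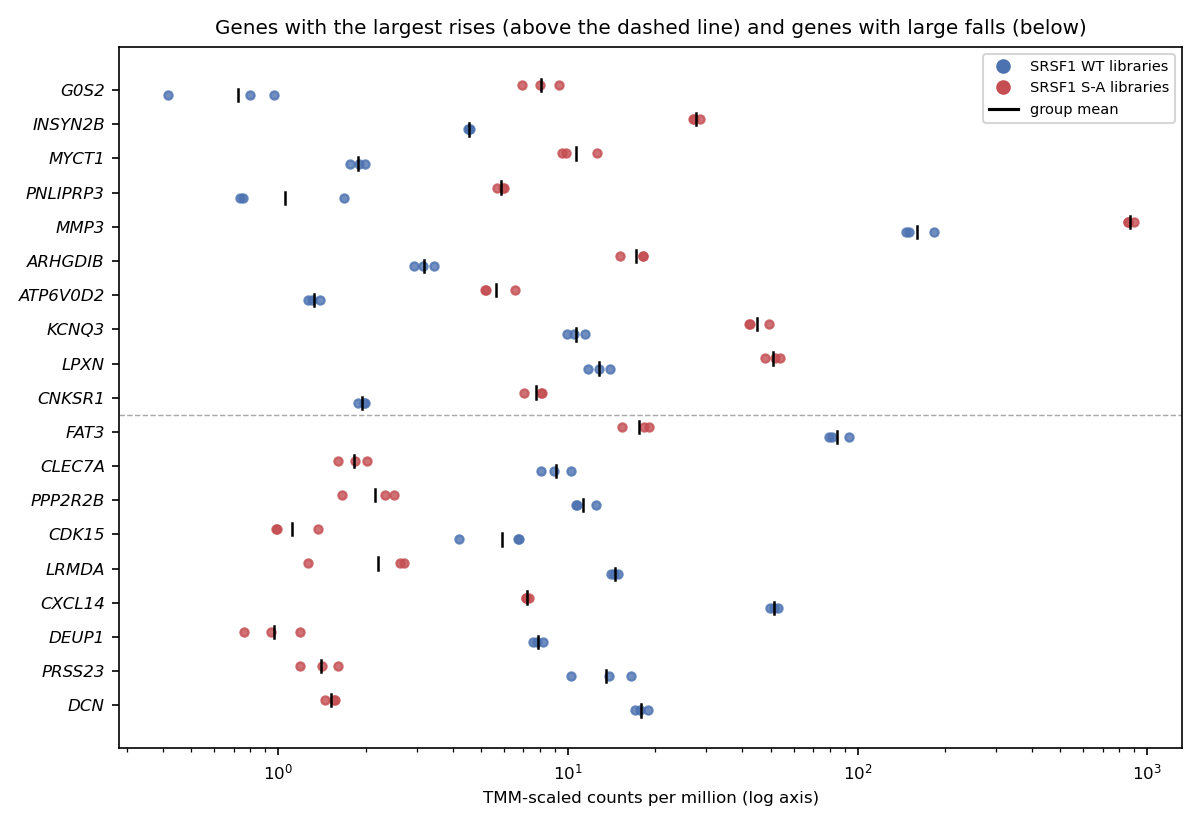
Level of the 10 genes with the largest rises (above the dashed line) and of genes with large falls (below it), in CPM with TMM scaling on a log axis; points are the 3 libraries of each group and black ticks the group means. The groups do not overlap for any gene drawn, from G0S2 at a mean of 0.727 in WT to MMP3 at 870 in S-A.

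Genes that build the ribosome were higher together in S-A cells. Of 90 genes for nucleolar proteins and ribosome biogenesis, 72 rose and 0 fell (75 and 1 adjusted over the list alone). Against all other genes the list had a camera adjusted p of 1.94e-17 with the preset correlation between genes of 0.01, and an adjusted p of 0.169 with an estimated correlation. Its median log2 fold change was 0.33, which is 1.25-fold. RRS1, which takes part in assembly of the large ribosomal subunit, rose from 32.3 ± 0.622 to 63.0 ± 1.05 CPM (SD, n = 3 per group). WDR43 and WDR3, which encode components of the small subunit processome, rose by 0.56 and 0.55 on the log2 scale.

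Genes for the proteins of the ribosome itself rose in 63 of 79 cases and fell in 0 (68 and 0 adjusted over the list alone), with a median of 0.30 on the log2 scale. The camera adjusted p was 4.35e-15, and the adjusted p was 0.342 with an estimated correlation. Examples were RPL14 (0.44), RPL32 (0.40) and RPL29 (0.35), with the log2 fold change in parentheses here and for the lists that follow. The share of ribosomal protein genes in all counts was 4.85 ± 0.181% in WT and 5.82 ± 0.0965% in S-A libraries (SD, n = 3 per group, exact permutation p = 0.1, 2-sided, the smallest that 3 against 3 allow). Among 24 genes for RNA polymerase I and its factors, which transcribe ribosomal RNA, 14 rose and 1 fell (15 and 1 adjusted over the list alone). This list had a camera adjusted p of 0.000594, and an adjusted p of 0.191 with an estimated correlation. The genes that rose included TAF1D (0.48), POLR1F (0.62) and POLR1C (0.48).

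Of 39 MYC target genes, 30 rose and 0 fell (32 and 0 adjusted over the list alone), among them PPRC1 (0.64) and the hexokinase gene HK2 (1.21). The list's median was 0.36, its camera adjusted p 1.02e-11 and its adjusted p 0.277 with an estimated correlation. It shares 17 measured genes with the list for ribosome biogenesis. Translation factor genes rose in 26 of 42 cases and fell in 2 (26 and 4 adjusted over the list alone), with a camera adjusted p of 1.82e-05 and an adjusted p of 0.342 with an estimated correlation. EIF5 (0.37), EIF3M (0.29) and ABCE1 (0.35) were among the rises. Host genes of small nucleolar RNAs rose in 4 of 7 measured cases and fell in 0, also when adjusted over the list alone, and 4 of the 7 are translation factor genes as well. Their camera adjusted p was 0.0447, their adjusted p was 0.342 with an estimated correlation, and the call was lost without WT replicate 1 (adjusted p = 0.0601), without S-A replicate 1 (adjusted p = 0.155), with the replicate block (adjusted p = 0.0603) and after a correction for GC content and gene length that was added once the data had been seen (adjusted p = 0.0777), within a range of 0.0175 to 0.342 over all camera alternatives.

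Genes of cell division were lower in S-A cells. Of 46 genes of mitosis and the G2 to M transition, 35 fell and 2 rose (37 and 3 adjusted over the list alone), with a median of -0.33. The camera adjusted p was 3.40e-09, and the adjusted p was 0.191 with an estimated correlation. The mitotic kinesin gene KIF20A fell from 94.4 ± 0.867 to 66.4 ± 2.24 CPM (SD, n = 3 per group), and DLGAP5 (-0.45) and the cell cycle transcription factor gene MYBL2 (-0.44) fell with it. Among 44 genes of DNA replication and S phase, 22 fell and 2 rose, and these counts were the same adjusted over the list alone. The median was -0.15, the camera adjusted p 0.00016 and the adjusted p 0.296 with an estimated correlation. Replication-dependent histone genes, of which 19 of the 59 listed were measured, fell in 8 cases and rose in 0 (9 and 0 adjusted over the list alone). Their camera adjusted p was 0.00508, and their adjusted p was 0.411 with an estimated correlation.

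Extracellular matrix genes fell in 39 of 57 cases and rose in 3 (39 and 4 adjusted over the list alone), with a median of -0.35. The camera adjusted p was 3.40e-09, and the adjusted p was 0.285 with an estimated correlation. Besides DCN, the lysyl oxidase gene LOXL4 fell from 424 ± 5.75 to 168 ± 0.237 CPM, and the fibrillar collagen gene COL3A1 from 246 ± 27.9 to 77.8 ± 1.91 (SD, n = 3 per group). Immediate early genes, which respond within minutes to growth factor signals, rose in 19 of 30 cases and fell in 2 (19 and 3 adjusted over the list alone). Their camera adjusted p was 9.91e-05, and their adjusted p was 0.285 with an estimated correlation. FOSL1 (1.52) and DUSP5 (1.32) were among them, as was KLF6, which rose from 47.6 ± 1.46 to 95.1 ± 5.66 CPM (SD, n = 3 per group). Inflammatory target genes of NF-kB rose in 16 of 24 measured cases and fell in 2 (17 and 2 adjusted over the list alone), MMP3 and SOD2 among the members. Their median was 0.41, their camera adjusted p 0.000238 and their adjusted p 0.285 with an estimated correlation.

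All 13 measured genes of the mitochondrial genome rose, also when adjusted over the list alone, with a median of 0.39. The camera adjusted p was 2.02e-06, and the adjusted p was 0.342 with an estimated correlation. MT-ND2 rose from 1366 ± 61.8 to 2164 ± 168 CPM (SD, n = 3 per group), and MT-ATP6 and MT-ND4L rose by 0.47 and 0.44 on the log2 scale. The mitochondrial share of all counts was 3.98 ± 0.0575% in WT and 4.91 ± 0.244% in S-A libraries (SD, n = 3 per group, exact permutation p = 0.1, 2-sided, the smallest possible). After a correction for GC content and gene length, added once the data had been seen, the median was 0.17 and 6 of the 13 rose. With that correction the list still passed camera at the preset correlation (adjusted p = 0.0436). Of 74 nuclear genes of oxidative phosphorylation, 16 rose and 4 fell (10 and 2 adjusted over the list alone), and that list did not pass (camera adjusted p = 0.0906).

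Genes of the core spliceosome were slightly higher as a group. Of 53 measured, 18 rose and 3 fell, also when adjusted over the list alone, with a median of 0.11, and with library totals alone 12 rose and 6 fell with a median of 0.066. The camera adjusted p was 0.00586, and the adjusted p was 0.285 with an estimated correlation. Factors and reported targets of nonsense-mediated decay rose in 15 of 28 measured cases and fell in 3 (16 and 4 adjusted over the list alone). Their camera adjusted p was 0.0011, and their adjusted p was 0.285 with an estimated correlation. SR proteins and their kinases, the family of SRSF1, rose in 9 of 27 cases and fell in 2, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0607). SRSF8 (0.30), SRRM1 (0.24) and SRSF4 (0.16) rose, the last with an adjusted p of 0.014 that was 0.122 to 0.124 on FPKM values and 0.0119 to 0.124 over all alternatives. Of 26 hnRNP genes, 11 fell and 3 rose (13 and 3 adjusted over the list alone; camera adjusted p = 0.0664). Genes reported as splicing targets of SRSF1 rose in 17 of 42 cases and fell in 6 (17 and 8 adjusted over the list alone; camera adjusted p = 0.0906).

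The lists for nucleolar caps and paraspeckles, redox, pH and p53 targets did not pass as groups, though single members changed. Of all tested genes 42.8% were called, so single changed members are not a result about these lists. Of 26 measured genes for nucleolar cap and paraspeckle components, 8 rose and 6 fell (8 and 7 adjusted over the list alone), with a camera adjusted p of 0.933. Among its members SOX9 (0.37) and PML (0.37) rose. On FPKM values the change of PML did not pass in the limma test, with adjusted p values of 0.0593 to 0.0640, within a range of 4.21e-05 to 0.0640 over all alternatives. Among 60 antioxidant and redox genes, 11 rose and 16 fell, also when adjusted over the list alone, with a camera adjusted p of 0.423. Mitochondrial superoxide dismutase SOD2 rose from 251 ± 6.51 to 486 ± 13.3 CPM, and SESN3 fell from 142 ± 5.71 to 75.3 ± 3.55 (SD, n = 3 per group). Genes of pH control and proton transport rose in 14 of 37 cases and fell in 8 (16 and 9 adjusted over the list alone; camera adjusted p = 0.361). Of 46 p53 target genes, 15 rose and 8 fell (16 and 9 adjusted over the list alone; camera adjusted p = 0.0592), with rises of PMAIP1 (0.67) and TIGAR (0.46) and a fall of DDB2 (-0.59).

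The remaining lists did not pass either. Hypoxia and glycolysis genes rose in 16 of 35 cases and fell in 7, also when adjusted over the list alone (camera adjusted p = 0.0855), and osteoblast genes fell in 7 of 18 and rose in 3 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0861). Genes of the integrated stress and unfolded protein response rose in 13 of 42 cases and fell in 13 (13 and 14 adjusted over the list alone; camera adjusted p = 0.839). The counts of rises and falls were 7 and 4 of 24 for heat shock proteins (7 and 5 adjusted over the list alone; camera adjusted p = 0.312), and 9 and 4 of 41 for autophagy and lysosome (8 and 3 adjusted over the list alone; camera adjusted p = 0.213). They were 10 and 6 of 35 for interferon-stimulated genes (10 and 7 adjusted over the list alone; camera adjusted p = 0.423), 3 and 6 of 29 for cholesterol biosynthesis, also adjusted over the list alone (camera adjusted p = 0.539), and 8 and 13 of 48 for DNA repair (10 and 13 adjusted over the list alone; camera adjusted p = 0.662). Markers of other cell types showed no common direction past the threshold. Epithelial markers rose in 1 of 8 measured cases and fell in 3 (1 and 4 adjusted over the list alone; camera adjusted p = 0.129), muscle markers rose in 2 of 7 and fell in 5, also adjusted over the list alone (camera adjusted p = 0.146), neuronal markers rose in 2 of 7 and fell in 3 (3 and 3 adjusted over the list alone; camera adjusted p = 0.616), and endothelial markers rose in 1 of 5 and fell in 2, also adjusted over the list alone (camera adjusted p = 0.749). Of the haematopoietic markers 4 were measured, too few for the test.

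Of the 35 tested lists 15 passed, 11 higher and 4 lower in S-A, and 0 passed camera with an estimated correlation, where 6 had an unadjusted p under 0.05. Splits of the libraries that mixed the groups still gave 8 to 13 lists past camera with the preset correlation. With fry, which asks whether a list's own genes move to one side and does not compare them with other genes, 29 passed. With library totals alone, the falls numbered 1 for ribosome biogenesis, 5 for translation factors, 2 for RNA polymerase I and 7 for heat shock proteins, and rises and falls were 10 and 8 for nuclear oxidative phosphorylation and 5 and 7 for autophagy and lysosome. Median, mean and test pointed to different sides in 4 lists. The test pointed up for the stress response (median -0.01, mean 0.05) and for the nucleolar cap list (median -0.01, mean -0.01), and down for neuronal (median -0.19, mean 0.08) and endothelial markers (median 0.04, mean 0.16).

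**Figure D3:**
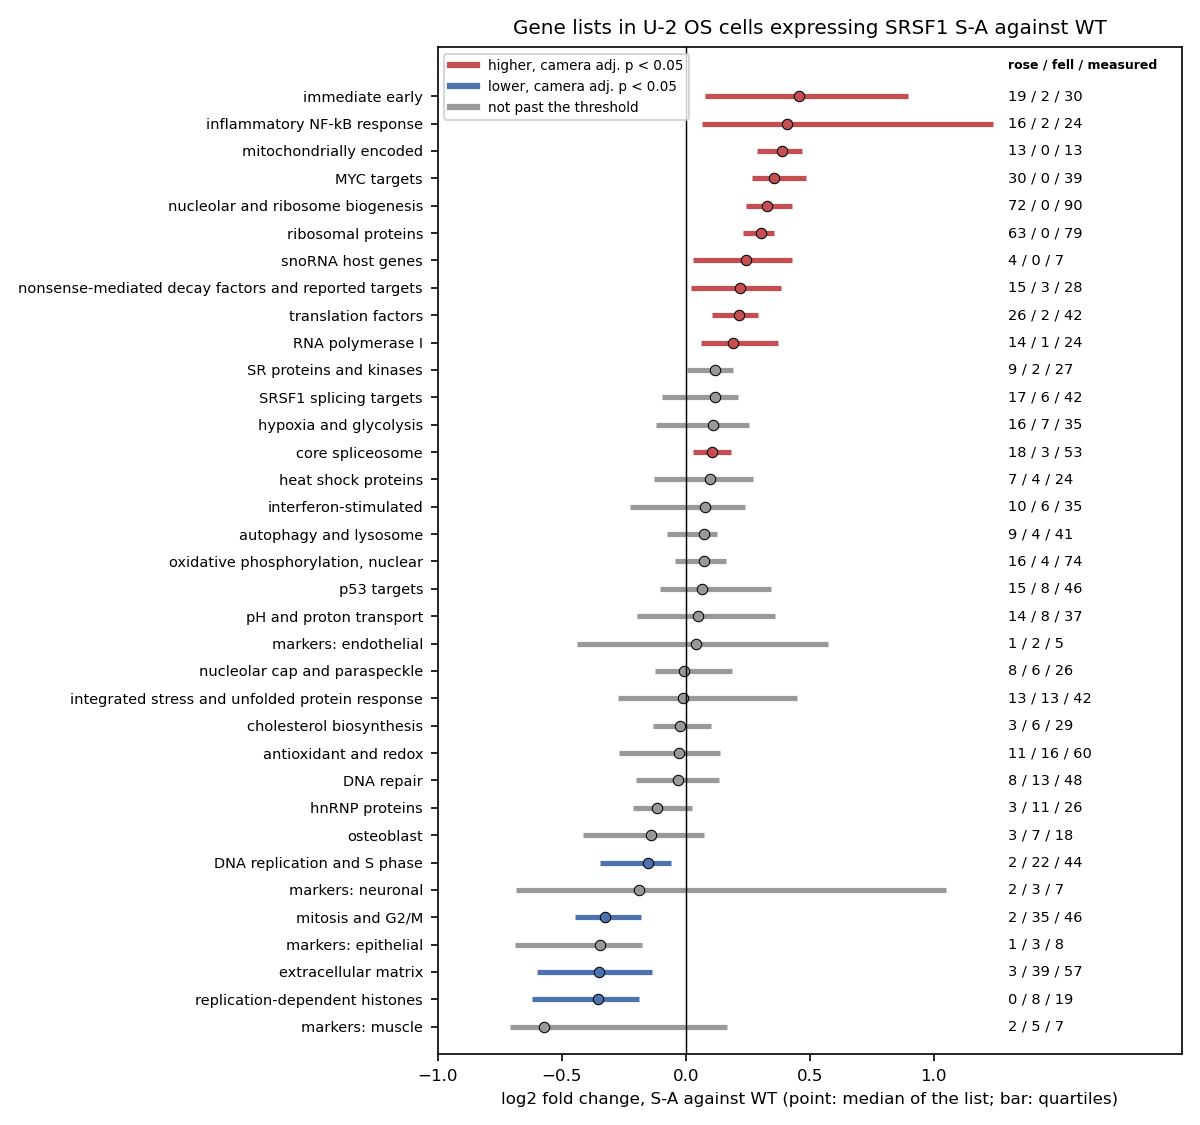
Log2 fold change of S-A against WT for the 35 tested gene lists, sorted by median; points are the medians over each list's measured genes, bars run from the lower to the upper quartile, and the numbers at the right count the genes that rose, fell and were measured. Red and blue lists passed camera with the preset correlation and grey lists did not; ribosome biogenesis lies at 0.33 with 72 rises, and mitosis at -0.33 with 35 falls.

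Splicing was compared between 3 libraries and 3 others in the authors' deposited table, which calls them sample set 1 and sample set 2 and does not say which of them is WT. The short coding exon of DST at 56468982 to 56468999 on chromosome 6, in a gene for a linker of the cytoskeleton, had inclusion levels of 0, 0.01 and 0.615 in the libraries of set 1 and of 0.821 to 0.887 in set 2 of the authors' deposited table (FDR 3.02e-08). The exon of the DNA repair gene RAD51D at 35106988 to 35107122 on chromosome 17 had inclusion levels of 0.25 to 0.385 in set 1 and 1 in every library of set 2 of the authors' deposited table, with a listed FDR of 0. In CERS4, a ceramide synthase gene, an exon of the untranslated region at 8210683 to 8210862 on chromosome 19 was at 0 to 0.375 in set 1 and 0.81 to 0.917 in set 2 of the authors' deposited table (FDR 0.000208). The level of 0 in set 1 replicate 1 rests on 0 inclusion and 7 skipping counts. In the other direction, the authors' deposited table gave 0.667 to 1 in set 1 and 0.32 to 0.366 in set 2 for the exon of the kinase gene PRKCD at 53165104 to 53165215 on chromosome 3 (FDR 0.00262). For PRKCD, set 1 held few counts, 9, 12 and 13 for inclusion and 0, 3 and 0 for skipping. In the authors' deposited table the levels were 0.676 to 1 against 0.333 to 0.389 for CC2D2A at 15479219 to 15479328 on chromosome 4 (FDR 0.0277), and 0.733 to 0.944 against 0.462 to 0.609 for CEP295, a centriole gene, at 93702776 to 93702919 on chromosome 11 (FDR 0.0104). Among these exons DST and RAD51D also passed an edgeR test on the junction counts, while the adjusted p of that test was 0.107 for CERS4, 0.186 for PRKCD, 0.163 for CC2D2A and 0.186 for CEP295.

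Exon skipping events passed an FDR under 0.05 and a difference of at least 0.1 in 116 of 42395 cases in 98 genes of the authors' deposited table. Inclusion was lower in set 1 for 83 of them and higher for 33 (28.4%, exact two-sided binomial p = 3.87e-06, which treats events as independent). The groups' inclusion levels did not overlap in 103 of the 116, the median size of the difference was 0.456, and the median junction count was 16.5 per library, with 54 events at 20 or more. An edgeR test on the junction counts called 34 events, 26 of them among the 116, and 25 of the 116 had too few counts for that test. The called number was 67 at an FDR under 0.01, and with 1 library left out the edgeR test called 14 to 25. The share with higher inclusion had an exact binomial p of 0.0574 without set 1 replicate 3, within a range of 3.87e-06 to 0.0574 over all alternatives.

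Alternative 3' splice sites passed in 21 of 4831 cases of the authors' deposited table, 9 higher and 12 lower in set 1 (exact two-sided binomial p = 0.664). In LIG1, which encodes a DNA ligase of replication, the use of 3 more bases at 48151337 to 48151339 on chromosome 19 was 0.089 to 0.179 in set 1 and 0.705 to 1 in set 2 of the authors' deposited table (FDR 6.70e-10). The LIG1 levels of set 1 rest on only 1, 2 and 1 inclusion counts and 10, 9 and 7 skipping counts. COX11, a factor for assembly of cytochrome c oxidase, had levels of 0.372 to 0.387 and 0.556 to 0.708 for the part from 54961313 to 54962915 on chromosome 17 in the authors' deposited table (FDR 0.0331), and the chromatin remodeller gene CHD4 had 0.643 to 0.679 and 0.787 to 0.87 at 6578118 to 6578135 on chromosome 12 (FDR 0.0341). Higher in set 1 of the authors' deposited table were the upstream sites of RPL22L1, a paralogue of a ribosomal protein gene, at 170868135 to 170868201 on chromosome 3 (0.228 to 0.246 against 0.114 to 0.134, FDR 0.0199) and of ZNF462 at 106932263 to 106932445 on chromosome 9 (0.286 to 0.429 against 0.083 to 0.158, FDR 0.0428). Of mutually exclusive exons 10 of 7448 passed, 6 higher and 4 lower (exact two-sided binomial p = 0.754), and GIGYF2 at 232724574 to 232724691 on chromosome 2 had levels of 0.361 to 0.748 in set 1 and 0 to 0.227 in set 2 of the authors' deposited table (FDR 0.049, adjusted p of the edgeR test 0.202). In the authors' deposited table alternative 5' splice sites passed in 4 of 2968 cases, 4 higher and 0 lower (exact two-sided binomial p = 0.125), and retained introns in 4 of 1081, 3 higher and 1 lower (exact two-sided binomial p = 0.625). Called events of these 4 types had a median of 5.17 to 8.25 junction counts per library. The edgeR test called 6 events of alternative 3' splice sites, 1 of mutually exclusive exons, 1 of alternative 5' splice sites and 0 retained introns, where 26 had an unadjusted p under 0.05 in the authors' deposited table.

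Among 42 genes reported as splicing targets of SRSF1 with 360 listed events, 2 events passed and 11 had an unadjusted p under 0.05 in the authors' deposited table. Of the 4 events listed for SRSF1, 0 passed. Exon 4, at 58005398 to 58005600, was included at 0.978 to 0.995 in set 1 and 0.998 to 1 in set 2 of the authors' deposited table. A stretch from 58005042 to 58005800, listed as a retained intron, had levels of 0.72 to 0.889 and 0.926 to 1 in the authors' deposited table (FDR 0.144). It contains exon 4, and its skipping counts are those of exon 4 (2, 4 and 7 in set 1, 0, 0 and 1 in set 2). These levels are therefore relative to few counts and are not shares of all SRSF1 RNA. Retention counts were 25 to 36 per library, against 626 to 1137 counts that include exon 4. The ratio of counts on the junction of exons 1 and 2 to the counts that include exon 4 was 1.63 to 1.66 in set 1 and 0.740 to 0.746 in set 2 of the authors' deposited table. The exon 4 counts sum the junctions on both its sides, so only the ratio's difference between the sets can be read. This ratio was chosen after its values were seen, and its exact permutation p was 0.1 (2-sided), the smallest that 3 against 3 allow.

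**Figure D4:**
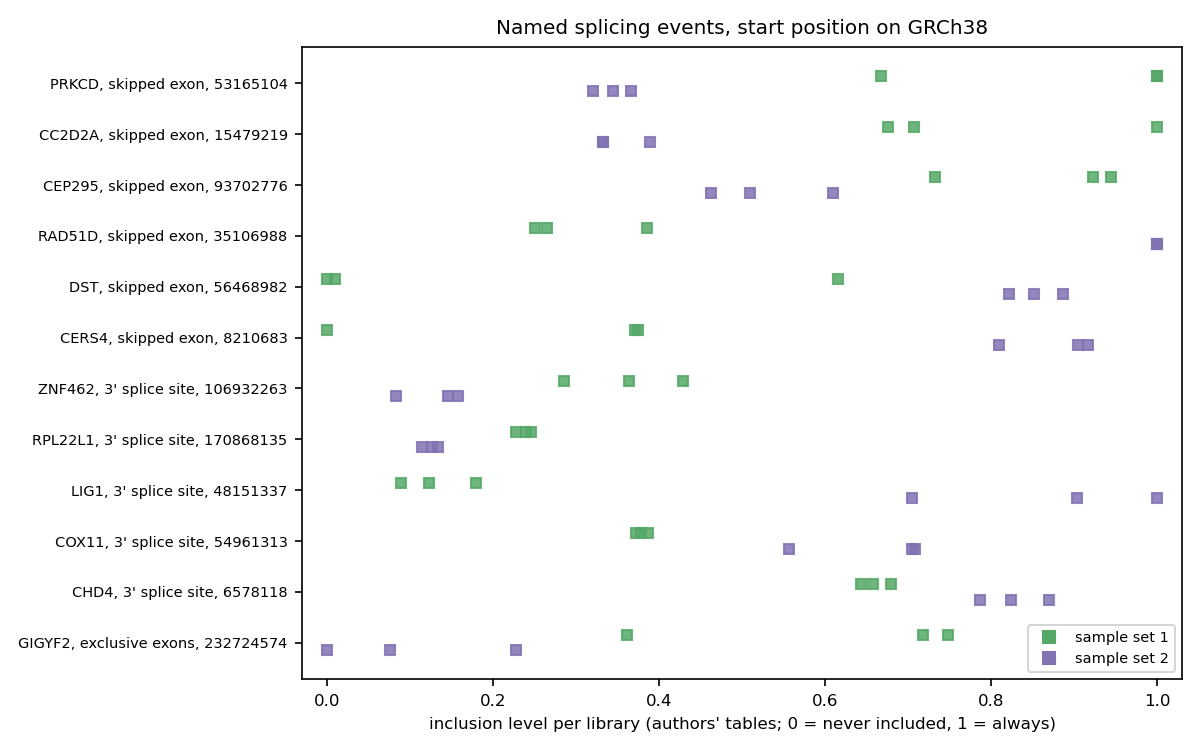
Inclusion level (0 to 1) per library of splicing events named above in the authors' deposited table, with the start position on GRCh38; green squares are the 3 libraries of set 1 and purple squares those of set 2, whose groups are not named. The sets do not overlap for any event drawn, with RAD51D at 1 in all libraries of set 2 and LIG1 at 0.089 to 0.179 in set 1.

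Genes with changed splicing were not shown to be those with changed levels. Of 127 genes with a called splicing event that were tested in both tables, 65 (51.2%) also changed in level, against 46.8% of the other genes tested in both. The expected number was 59.4 of the 9987 genes, the odds ratio was 1.19 (95% interval 0.83 to 1.72), and Fisher's exact test gave a two-sided p of 0.326.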

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

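The correction for GC content and gene length, the use of 1 event per gene and the use of events with 1 reading were chosen after the results were seen. Between 5029 and 6653 genes passed under all alternatives, against 6340, and both filters on low counts removed 0 genes and so tested nothing. The replicate block gave 5480 genes, although replicate numbers were not shown to mark pairs (correlations across genes of -0.03, 0.0046 and -0.10 between equal numbers). Library totals moved the median of all genes to -0.04 on the log2 scale and lowered the share of rises from 49.5% to 41.2%. The 54 named genes other than SRSF1 kept direction and call in 912 of 918 comparisons, and the 6 others were SRSF4 and PML on FPKM.

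SRSF1 passed with the DESeq2 Wald test (log2 fold change 0.19), on FPKM with a pseudocount of 0.1 with and without a filter (0.30 and 0.30) and of 1 (0.30), and without S-A replicate 3; with single libraries left out its log2 fold change was 0.10 to 0.25. Of the lists, 0 passed camera with an estimated correlation and 29 passed fry, against 15, and the causes were not tested. The estimate was above the preset 0.01 in every passing list but RNA polymerase I. There it was -0.005, and the unadjusted camera p still went from 0.000187 to 0.0143. A higher correlation therefore cannot account for the larger p of that list. With single libraries left out 14 to 20 lists passed.

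Called exon skipping events numbered 67 at an FDR under 0.01, 54 with 20 or more junction counts and 34 with edgeR, and 14 to 25 with edgeR and 1 library less, with shares of higher inclusion of 6.25% to 22.7%. Of the 116 events, 112 had 1 reading, and the share was 29.5% in these and 30.6% with 1 event per gene. For alternative 3' splice sites the counts were 12 (FDR under 0.01), 5 (20 junction counts), 6 (edgeR) and 1 to 4 (edgeR with 1 library less), against 21. For alternative 5' splice sites they were 1, 0, 1 and 0 to 4, against 4 in the authors' table and 77 at an unadjusted p under 0.05. For mutually exclusive exons they were 2, 1, 1 and 0 to 6, against 10 and 148 unadjusted. For retained introns they were 3 (FDR under 0.01), 0 (20 junction counts), 0 (edgeR) and 0 to 1, against 4 and 26 unadjusted. Apart from the stricter FDR, these settings use fewer events or libraries. Those with edgeR also use another test than the authors' FDR, so counts with 1 library less compare with the full edgeR counts. In simulated data the edgeR test found 1.49% of shifts of 0.1 and the gene test 4% of changes of 1.2-fold. For the gene test, far fewer genes were changed there than were called in the real data, so that share does not carry over. The share of the edgeR splicing test does not carry over to calls by the authors' FDR, which was not simulated.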

Other observations

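All tests in this part were chosen after the results they measure had been seen.

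The authors' deposited gene ontology table listed 2734 terms, of which 1455 had an adjusted p under 0.05, for a list of 4506 genes. Its first term was cell division, with 877 genes (19.5% of the list) against 2781 of 19779 background genes (14.1%) and an authors' adjusted p of 2.50e-27 in the authors' deposited table. Exon skipping events outside the called ones leaned to the same side as the called ones. Among 1189 that did not pass, with 20 or more junction counts and a difference of at least 0.1, 439 were higher and 750 lower in set 1 (36.9% higher, exact two-sided binomial p = 1.54e-19, which treats events as independent). Called events with more than 100 junction counts per library were higher in set 1 in 3 cases and lower in 22. Along the genome, the medians of 246 windows of 10 megabases ran from -0.19 to 0.18 on the log2 scale, and 152 of 200 shuffles of the genes gave a median as large.

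Genes for ribosome biogenesis and ribosomal proteins were higher and genes for mitosis lower in S-A cells, and genes of the mitochondrial genome were higher. A correction for GC content and gene length left the medians at 0.33, 0.28 and -0.33 on the log2 scale. This argues against that trend as the whole cause for these 3 lists. Library totals alone gave 0.29, 0.26 and -0.37, and 0.345 for the mitochondrial genes. These values cannot decide about library size, since the TMM factors were only 0.978 to 1.02 and could not have moved the medians far. For the mitochondrial genes, the correction lowered the median from 0.39 to 0.168 with 6 of 13 still rising (camera adjusted p at the preset correlation 0.0436). A part due to short length and GC content therefore cannot be told apart from a change in level. The form of SRSF1 and any other difference between the cultures or clones of the 2 groups both stay open, since the design holds no sample that separates them.

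The gene ontology terms of the splicing table may rest on how its genes were chosen. All 854 cell division genes of that table that the gene table holds had an event with a difference over 0.1, as had all 3977 of its genes that were found there, and only 114 of these were among the 130 genes with an event past the FDR, which is consistent with a choice by size of the difference without the FDR. Against the 9987 genes that have an event, the odds ratio of cell division was 1.19 in place of 1.70, still with a two-sided Fisher's exact p of 0.000834 (adjusted over 10 terms 0.00104), so how much of the authors' excess came from the background cannot be told apart from an excess of these genes. Among genes with a called event 37 of 127 carried the cell division term in the deposited annotation (29.1% against 18.2%, odds ratio 1.85, Fisher's exact p = 0.00259, adjusted 0.0234). The term is broad there, with 1833 of the 9987 genes that have an event. The 37 include AAK1, GNAS and ZNF12. Draws matched on the number of events and depth gave a median of 25 (95% range 17 to 34, permutation p = 0.0088, adjusted over 10 terms 0.053), so an excess beyond depth stays open.

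In SRSF1 the counts on the junction of exons 1 and 2 were 1028 to 1319 in set 1 and 563 to 844 in set 2. Those that include exon 4 were 626 to 793 and 755 to 1137, ranges that overlap and are not scaled for depth. The ratio of the first counts to the second, in which depth cancels, differed between the sets by a shift of 1.14 on the log2 scale. A position bias along transcripts would shift other genes alike, but over 2408 other genes the median of the same shift was -0.019 (quartiles -0.11 and 0.06). Only 5 of them (0.208%) shifted as much, which is consistent with an expressed copy of SRSF1 that does not cover the gene evenly and differs between the groups, a hypothesis these tables cannot settle. The counts for exon 4 in set 2 had lost their commas and have several readings, of which the evenest was taken. Neither the labels nor the table headers say which set is S-A, so the shift was not assigned to a group.

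The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 6340 genes and the highest other 5, and 1 of 10 splits gave as many as the real one. For lists the real split gave 15, every other split gave 8 to 13, and 1 of 10 gave as many as the real one. Those other splits called at most 5 genes. The number of lists past camera with the preset correlation therefore hardly sets the real groups apart. For exon skipping events called by edgeR the real split gave 34 and the highest other 5, and 1 of 10 gave as many.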
